A study of Mus musculus with 6 samples.

How the data were processed

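Total RNA of 6 samples of cultured mouse spleen cells, 3 given buffer and 3 given COL17A1, was labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels' protocols. The arrays were read with Agilent Feature Extraction 12.0.3.1, per the submitters' processing notes and the file headers. The deposited files hold, per the file headers, a processed intensity of each spot, from which the software had subtracted background and spatial trend and in which it had replaced very small values by a surrogate, and the raw mean and local background intensity. The processed intensity was not normalised between arrays, per the file headers. Flags for spots well above background, for saturation and for outliers were used as the deposited files give them. Each array holds 59305 non-control spots of 56605 probes under 36870 gene names. The reference table, of another build than the mm9 named in the file headers, was used for names only: 42762 probes carried a name that is a symbol in it and 1038 a synonym. Names from the files were kept otherwise, and coordinates are those of the files.

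The log2 of the processed intensity was taken and the 75th percentile of each array over non-control spots was subtracted. Spots flagged as outliers were left out, which left 120 tested genes with a missing array, and spots of 1 probe were averaged. Probes were tested if well above background on at least 3 of the 6 arrays in either group, and a gene was represented by its brightest probe over all arrays, giving 21288 genes from 32450 probes. The linear model and moderated test of limma 3.58.1 in R 4.3.3 compared the groups with no covariate, and p-values were adjusted after Benjamini and Hochberg with a threshold of 0.05. The model had 4 residual and 1.60 prior degrees of freedom. Where a gene was well above background on no array of a group, its change is given as a bound. The bound sets the brighter group's mean against the mean, over the dim group's arrays, of the higher of the lowest signal among probes well above background and the gene's own signal, and it holds for the processed intensity only.

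The 19 gene lists and 14 marker lists, the design, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 15 largest rises and the 15 largest falls in log2 change among called genes with a symbol whose groups did not overlap, up to 4 members of smallest p of each list, and 12 genes fixed by name: Col17a1, Itga6, Itgb4, Tnf, Il1b, Il6, Cxcl2, Ccl3, Ccl4, Ifng, Nfkbia and Cd69. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over all 33 lists. Camera with an estimated correlation and fry were alternatives. Other alternatives were quantile normalisation, scaling to the median, cyclic loess, normexp background correction with an offset of 50, other filters on dim probes, the mean of probes or each probe on its own, a trended and robust variance, array weights, outlier spots kept, other thresholds, lists without shared genes, a replicate block and leaving out arrays. A fit without the 2 arrays that the software's quality report marked for evaluation, control replicate 3 and COL17A1 replicate 2, was chosen after seeing the data. Their negative control spread was 30.8 and 32.7, against 11.1 to 19.6 for the others.

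No 2 arrays held identical signals. The labels do not say that equal numbers share a mouse, so no block was used in the main fit. Deviations from the group means showed no pairing by number, which with 3 arrays per group cannot exclude a shared mouse. The steps were tested on simulated data of 21168 genes with 50 genes changed at each size. Recovery was 60% at a log2 change of 0.5, 88% at 1, 94% at 2 and 98% at 3, with 6 false calls among 176. The raised list was called and 0 of 32 unchanged lists were. In the simulation genes varied independently, so it cannot show how often lists of correlated genes are called falsely. It also changed few genes, whereas 49.6% were called in the data, so its rates need not carry over. For 284 probes spotted 10 times and above background, the median SD within an array was 0.043 to 0.048 on the log2 scale. For the means of these probes over their spots, the median SD between arrays was 0.030 within the control and 0.033 within COL17A1. The number of arrays limits the precision of every value. Probes outside the filter, and list members with no probe passing it, were not tested in the main fit. Such probes entered the scaling of the arrays, the lowest signal used for the bounds and the alternative without that filter. Control spots other than the spike-in RNAs were not used here. Some genes that the rule takes are not reported here. Figures were drawn with matplotlib 3.10.9.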

Results

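Gene expression was measured in cultured spleen cells of male C57BL/6N mice, an inbred laboratory strain, aged 6 months. Collagen XVII, the product of COL17A1, is a transmembrane collagen best known from the hemidesmosomes that fasten basal skin cells to the layer beneath. The spleen cells, freed of red cells by ammonium chloride lysis, received recombinant human COL17A1 at 0.4 µg/mL in 3 samples and phosphate-buffered saline in the other 3, called the control. The series design gives the stimulation as 3 hours, whereas the sample descriptions give a contact time of 4 hours. Each sample was hybridised to its own 1-colour array, and the 6 arrays lay on 1 slide that was scanned once. Between 30772 and 37902 of the 59305 non-control spots of an array were well above background, and no spot was saturated. The titles number the spleens 1 to 3 in each group, and nothing in the labels says that the samples came from separate animals, so the p-values measure the spread between these samples, which may be technical.

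The comparison asks which transcripts differ between spleen cells given COL17A1 and those given buffer. Among the largest rises with COL17A1 were those of inflammatory mediators: Tnf, the gene of tumour necrosis factor, rose by 5.93 ± 0.07 (SE) on the log2 scale, Ifng, the gene of interferon gamma, by 6.39 ± 0.08, and Ptgs2, the gene of the inducible cyclooxygenase, by 7.34 ± 0.05. Among the largest falls, Rab7b, a gene of endosomal transport, fell by 4.43 ± 0.21 from its brightest probe and Cx3cr1, the fractalkine receptor, was at least 8.09-fold lower, being not well above background with COL17A1 (log2 change of -1.82 with normexp, under that bound). Among 21288 genes tested with limma, 4813 were higher and 5738 lower with COL17A1 at a Benjamini-Hochberg adjusted p under 0.05. Changes of at least 2-fold made up 923 of the higher and 920 of the lower genes. The groups did not overlap in 59.0% of all genes tested, where chance gives 10% for 3 arrays against 3. The median within-group SD over genes was 0.076 for the control and 0.093 for COL17A1, and the median log2 change over all genes was -0.03. Across the 29276 spots above background on all arrays, the SD of the log2 difference between arrays was 0.158 to 0.181 within the control, 0.279 to 0.306 within COL17A1 and 0.581 to 0.610 between the groups.

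**Figure D1:**
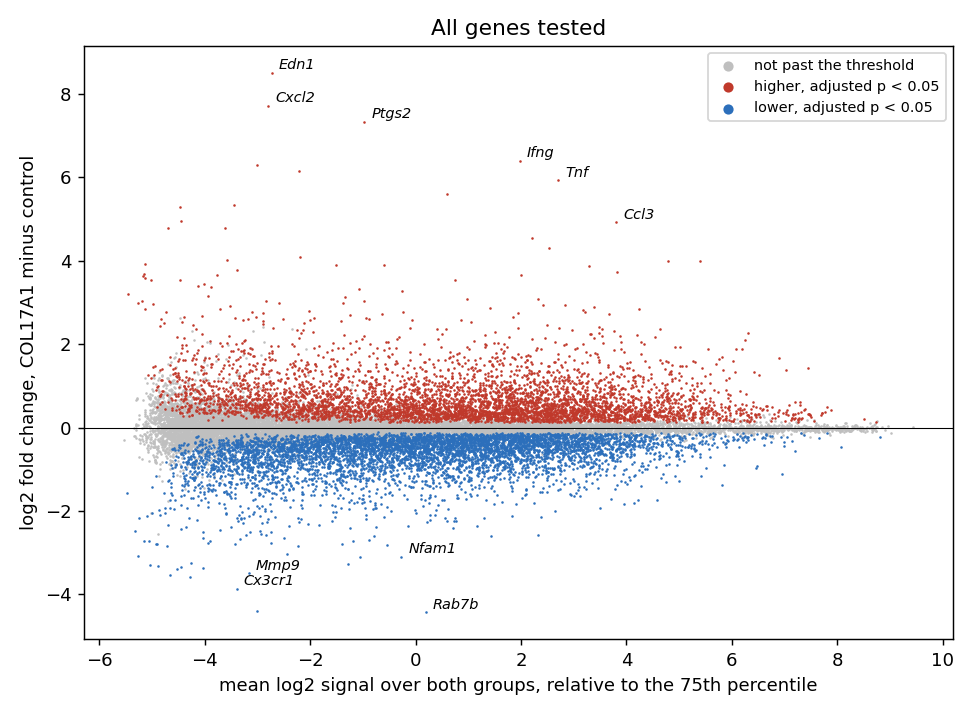
Log2 fold change (COL17A1 minus control) of every gene tested against its mean log2 signal over both groups, relative to the 75th percentile of each array. Each point is 1 gene; red points (4813 genes) were higher and blue points (5738 genes) lower at adjusted p under 0.05, and grey points did not pass. Points of genes not well above background in a group show fitted values, which are no bounds.

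The other genes with the largest rises under the fixed rule were mostly cytokine and chemokine genes. Il6 rose by 4.55 ± 0.05, Ccl3, a chemokine of macrophages, by 4.93 ± 0.04 and Tnfsf15, a member of the tumour necrosis factor family, by 5.61 ± 0.13 on the log2 scale. Edn1, the gene of the vasoconstrictor endothelin, was not well above background on any control array and was at least 94.8-fold higher with COL17A1, as was Cxcl2, a neutrophil-attracting chemokine, at least 69.1-fold. The same kind of bound was at least 19.2-fold for Cxcl1, 9.31-fold for Csf3, 8.45-fold for Il17a and 6.69-fold for Htra4, each not well above background in the control. Il1a (6.31 ± 0.75) and Ifnb1 (6.15 ± 0.48) were well above background on 1 of the 3 control arrays, and Ptgs2 on 2. Their values are sensitive to the background correction, with 3.52 for Il1a, 4.13 for Ifnb1 and 5.67 for Ptgs2 by normexp. Without control replicate 1 Il1a stood at 7.13, and without control replicate 2 at 5.62. Gm33627 was called higher and not well above background in the control, but only 2 COL17A1 arrays gave a usable spot, at 0.26 and -2.70 on the scaled log2 signal, so no bound is given. The bounds hold for the processed intensity only. By normexp, whose offset of 50 shrinks the change of dim spots, the log2 change was 4.95 for Edn1, 4.50 for Cxcl2, 2.61 for Cxcl1, 2.12 for Csf3, 1.74 for Il17a and 1.7 for Htra4, each smaller than its bound, and 2.22 for Gm33627.

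The 2 probes of Rab7b differed, at -4.43 and -1.43, and their mean gave -2.93. Among the other genes with the largest falls, B3gnt8 fell by 3.27 ± 0.11, Nfam1, an immune receptor with an activation motif, fell by 3.1 ± 0.10, Tmem86a fell by 3.09 ± 0.10 and Gm15880 fell by 3.03 ± 0.11 on the log2 scale. With normexp background correction B3gnt8 stood at -2.61 and Gm15880 at -1.97. The genes named next were not well above background with COL17A1 and therefore have bounds. Mmp9, a gelatinase, was at least 8.34-fold lower, Kcnj10 at least 3.96-fold, Hfe, a regulator of iron uptake, at least 3.59-fold, Snx24 at least 3.27-fold and Scrg1 at least 3.13-fold. Gm10561 was at least 2.38-fold, Lrrc14b at least 2.14-fold and Arl11 at least 1.68-fold lower, likewise not well above background with COL17A1. By normexp the log2 change was -1.75 for Mmp9, -1.37 for Kcnj10, -1.15 for Hfe, -0.96 for Snx24, -1.06 for Scrg1, -0.98 for Gm10561 and -0.89 for Lrrc14b, each under its bound. The adjusted p from limma was at most 0.0106 for every gene of these 2 sets of 15.

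Inflammatory cytokine genes rose as a group. Of 20 measured members, 19 were higher, 0 lower and 1 not called, and 19 were higher when adjusted over the list alone. The median log2 change was 2.65, or 2.51 with members below background at their bound. Il1b rose by 3.88 ± 0.05 and Tnfsf9, a costimulatory ligand, by 3.09 ± 0.05. The list passed limma's camera test (Benjamini-Hochberg adjusted p = 1.6e-13). T helper cytokine genes also rose, with 7 of 9 measured members higher, 0 lower and 2 not called, and 7 higher adjusted over the list alone. The 2 not called were Il4 and Il13. Il2, Il3, Il5, Il9 and Il31 were not tested, since their probes did not pass the background filter. Il17a and Il17f passed it through the COL17A1 arrays alone. Genes that stay off in both groups thus could not count against the rise. Il22, a cytokine that acts on epithelia, rose by 4.09 ± 0.10, being well above background on 2 of 3 control arrays, and Lta, the lymphotoxin gene, by 2.11 ± 0.05. Il22 ranged from 2.76 with normexp to 6.34 with the mean of its 2 probes. Their median was 2.11, or 1.38 with bounds, at a limma camera adjusted p of 2.5e-04 (adjusted p = 0.0934 with an estimated correlation).

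Chemokine genes rose as a group with exceptions. Of 20 measured members 15 were higher, 3 lower and 2 not called, and adjusted over the list alone 16 were higher and 3 lower. Ccl4 rose by 3.99 ± 0.04 and Cxcl10, an interferon-induced chemokine, by 3.99 ± 0.05. The median log2 change was 1.32 at a limma camera adjusted p of 3.5e-06 (adjusted p = 0.145 with an estimated correlation).

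Every measured gene of the NF-kB list, which holds targets and feedback inhibitors of that transcription factor, was higher: 22 higher, 0 lower and 0 not called, with 22 higher adjusted over the list alone. Nfkbia, which encodes an inhibitor of NF-kB, rose by 1.89 ± 0.05, Nfkbiz by 3.67 ± 0.04, Cd40 by 3.08 ± 0.06 and Icam1, an adhesion molecule, by 2.05 ± 0.05. The median was 1.44 at a limma camera adjusted p of 1.3e-15. The type I interferon response list rose likewise, with 27 higher, 0 lower and 0 not called, and 27 higher adjusted over the list alone. Mx1 rose by 2.85 ± 0.04, Mx2 by 2.78 ± 0.04, Ifit2 by 2.38 ± 0.05 and Cmpk2 by 2.16 ± 0.04, all of them antiviral genes. The median was 1.33 at a limma camera adjusted p of 4.5e-17.

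Genes that bacterial endotoxin is known to induce early rose too, and the protein was stated to hold less than 1 endotoxin unit per µg, which at the dose used allows up to 0.4 units per mL. Of 29 measured members 25 were higher, 2 lower and 2 not called, the same counts of 25 and 2 adjusted over the list alone. The median was 2.60 at a limma camera adjusted p of 3.5e-14 (adjusted p = 0.0934 with an estimated correlation). Ptgs2, Il6, Il1b and Tnf, given above, are its members of smallest p. No sample with endotoxin alone or with heated protein was analysed here.

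The interferon gamma and class II presentation list rose, with 12 of 22 measured members higher, 3 lower and 7 not called, and 12 higher and 3 lower adjusted over the list alone. Socs1, a feedback inhibitor of cytokine signalling, rose by 2.71 ± 0.04, Gbp5 by 2.24 ± 0.07, Iigp1 by 1.82 ± 0.05 and Igtp by 1.32 ± 0.04, the last 3 being interferon-induced GTPases. The mean of its 2 probes gave 1.61 for Gbp5. The members lower were class II genes or their regulator, Ciita, H2-DMa and H2-DMb1, named after their values were seen, and they fell by 0.95, fell by 0.70 and fell by 0.29. The other class II presentation genes H2-Aa (-0.005), H2-Ab1 (0.10), H2-Eb1 (-0.08) and Cd74 (0.07) were not called, so class II genes did not fall as a set. The median was 0.33 at a limma camera adjusted p of 5.6e-04 (adjusted p = 0.206 with an estimated correlation).

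Immediate early genes, among the first genes that a stimulus induces, rose in 16 of 23 measured members, with 3 lower and 4 not called. Adjusted over the list alone, 16 were higher and 3 lower. Myc rose by 2.94 ± 0.07, Jun by 2.23 ± 0.06, Nr4a1 by 1.37 ± 0.05 and Junb by 1.29 ± 0.05. The 3 lower were Egr3 (-0.86), Egr2 (-0.29) and Nr4a2 (-0.25), and Fos (-0.12) and Fosb (-0.20) were among those not called. These genes were named after their values were seen. The median was 0.47 at a limma camera adjusted p of 3.5e-05 (adjusted p = 0.145 with an estimated correlation). Lymphocyte activation genes rose in 14 of 19 measured members, with 3 lower and 2 not called, and 14 higher and 3 lower adjusted over the list alone. Cd69, an early activation antigen, rose by 4.31 ± 0.05, Batf by 2.20 ± 0.05, Il2ra, the interleukin 2 receptor alpha chain, by 1.89 ± 0.04 and Cd86 by 1.28 ± 0.04. The 3 lower members were Pdcd1 (-0.67), Gata3 (-0.58) and Icos (-0.49), and the 2 not called were Ctla4 and Tnfrsf18, likewise named afterwards. The median was 0.52 at a limma camera adjusted p of 2.5e-04 (adjusted p = 0.0934 with an estimated correlation).

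**Figure D2:**
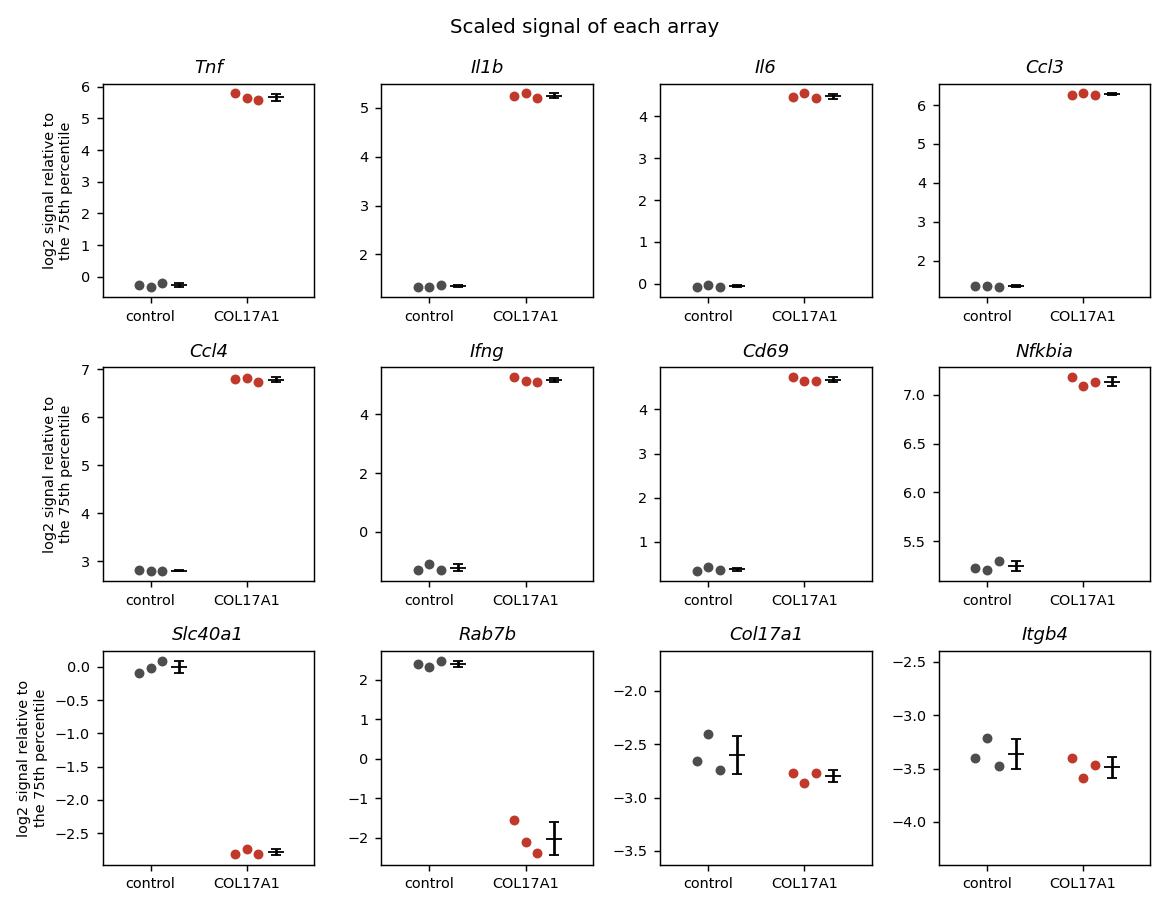
Log2 signal relative to the 75th percentile of the array for 12 genes, with 1 point per array (3 control in grey, 3 COL17A1 in red) and the mean with its SD beside each group. The axes differ between panels and do not start at 0. The groups are apart for Tnf, Il1b, Il6, Ccl3, Ccl4, Ifng, Cd69, Nfkbia, Slc40a1 and Rab7b, whereas those of Itgb4 (-0.12) overlap. The groups of Col17a1 (-0.20) lie close together without overlap, and neither of these 2 genes passed the test.

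The mouse gene Col17a1 itself had a log2 change of -0.20 ± 0.10 and was not called (limma adjusted p = 0.156), with a 95% interval of -0.44 to 0.05. Its probe lies on chromosome 19 from 47721454 to 47721513 in mm9, the build named in the file headers. Itgb4, the integrin chain of hemidesmosomes, had a change of -0.12 ± 0.09 and was not called either. The list of collagen XVII partners, collagen receptors and hemidesmosome genes did not move as a group: of 17 measured members 4 were higher, 4 lower and 9 not called, with 3 higher and 4 lower adjusted over the list alone. Itga5, a fibronectin receptor chain, rose by 1.37 ± 0.06, while Plec, the cytoskeletal linker plectin, fell by 0.80 ± 0.04 and the tetraspanin gene Cd151 fell by 0.95 ± 0.05. Itga6 was called higher at 0.72 ± 0.04 from its brightest probe, but its 4 probes ranged from -1.69 to 0.72 and the mean of its probes gave -0.89, so its direction depends on the probe. The list's median was -0.07, its mean 0.07 and its camera direction up (limma adjusted p = 0.968), so median and test differ in sign.

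Matrix proteases and their inhibitors moved both ways, with 5 of 19 measured members higher, 10 lower and 4 not called, and 6 higher and 10 lower adjusted over the list alone. Mmp14 rose by 0.91 ± 0.06, whereas Timp2 fell by 1.94 ± 0.06, or had -1.35 by the mean of its 2 probes. The median was -0.20 and the list was not called (limma camera adjusted p = 0.616), whereas fry called it lower (limma adjusted p = 1.1e-04).

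Among stress and metabolic lists, cholesterol synthesis genes rose most evenly: 15 of 17 measured members were higher, 0 lower and 2 not called, with 15 higher adjusted over the list alone. Idi1 rose by 1.15 ± 0.06, Hmgcs1 by 1.12 ± 0.06 and Sqle by 1.02 ± 0.06. The median was 0.73 at a limma camera adjusted p of 3.0e-07 (adjusted p = 0.272 with an estimated correlation). The unfolded protein and integrated stress response list rose too, with 10 of 16 higher, 2 lower and 4 not called, and 10 and 2 adjusted over the list alone. Chac1, a target of ATF4, rose by 1.56 ± 0.10, Psat1, a serine synthesis enzyme, by 1.07 ± 0.04 and the chaperone gene Hspa5 by 0.91 ± 0.04. The median was 0.56 at a limma camera adjusted p of 0.00251 (adjusted p = 0.374 with an estimated correlation).

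Other such lists were not called by camera, which compares a list with all other genes. Against no change, fry called heat shock (limma adjusted p = 0.00291), hypoxia and glycolysis (0.0162), p53 and apoptosis (1.1e-04) and cell cycle genes (5.4e-04), all higher. Camera with every probe on its own called heat shock (limma adjusted p = 0.00271), p53 and apoptosis (3.0e-04) and cell cycle genes (0.00484) higher too. Heat shock genes had 7 of 13 measured members higher, 2 lower and 4 not called, the same adjusted over the list alone, with Hspd1 up by 0.82 ± 0.05 and Hsp90aa1 by 0.84 ± 0.08 (limma camera adjusted p = 0.160). Hypoxia and glycolysis genes had 8 of 23 higher, 6 lower and 9 not called, or 8 and 7 adjusted over the list alone. Hk2, a hexokinase, rose by 2.24 ± 0.07 and Ankrd37 fell by 1.84 ± 0.07, and Vegfa was called at 1.52 although its probes ranged from -0.02 to 1.56 (limma camera adjusted p = 0.616). Of 14 oxidative stress genes and metallothioneins, 6 were higher, 6 lower and 2 not called, the same adjusted over the list alone, and the median of 0.04 and mean of -0.24 differ in sign (limma camera adjusted p = 0.976). In that list Slc30a1, a zinc exporter, fell by 2.04 ± 0.11, Mt1 fell by 1.22 ± 0.08 and Mt2 fell by 1.18 ± 0.08, while Txnrd1 rose by 0.76 ± 0.05. The 2 probes of Mt1 differed, at -1.22 and -0.52, and their mean gave -0.87. The p53 and apoptosis list had 9 of 17 higher, 6 lower and 2 not called, the same adjusted over the list alone (limma camera adjusted p = 0.143). Its Bcl2l1, a survival factor, rose by 2.01 ± 0.05, Cdkn1a by 1.66 ± 0.06 and Fas by 1.23 ± 0.04, while Sesn1 fell by 1.44 ± 0.04. Cell cycle genes had 8 of 21 higher, 4 lower and 9 not called, or 9 and 4 adjusted over the list alone, with Ccnd2 up by 2.11 ± 0.04 and Mki67 by 0.59 ± 0.05 (limma camera adjusted p = 0.0900). Ribosomal protein genes had 0 of 20 higher, 1 lower and 19 not called, and 0 and 0 adjusted over the list alone, with a median of -0.01 (limma camera adjusted p = 0.917). The 1 gene lower was Rps20, at -0.23 from its brightest probe and 0.18 from the mean of its probes.

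**Figure D3:**
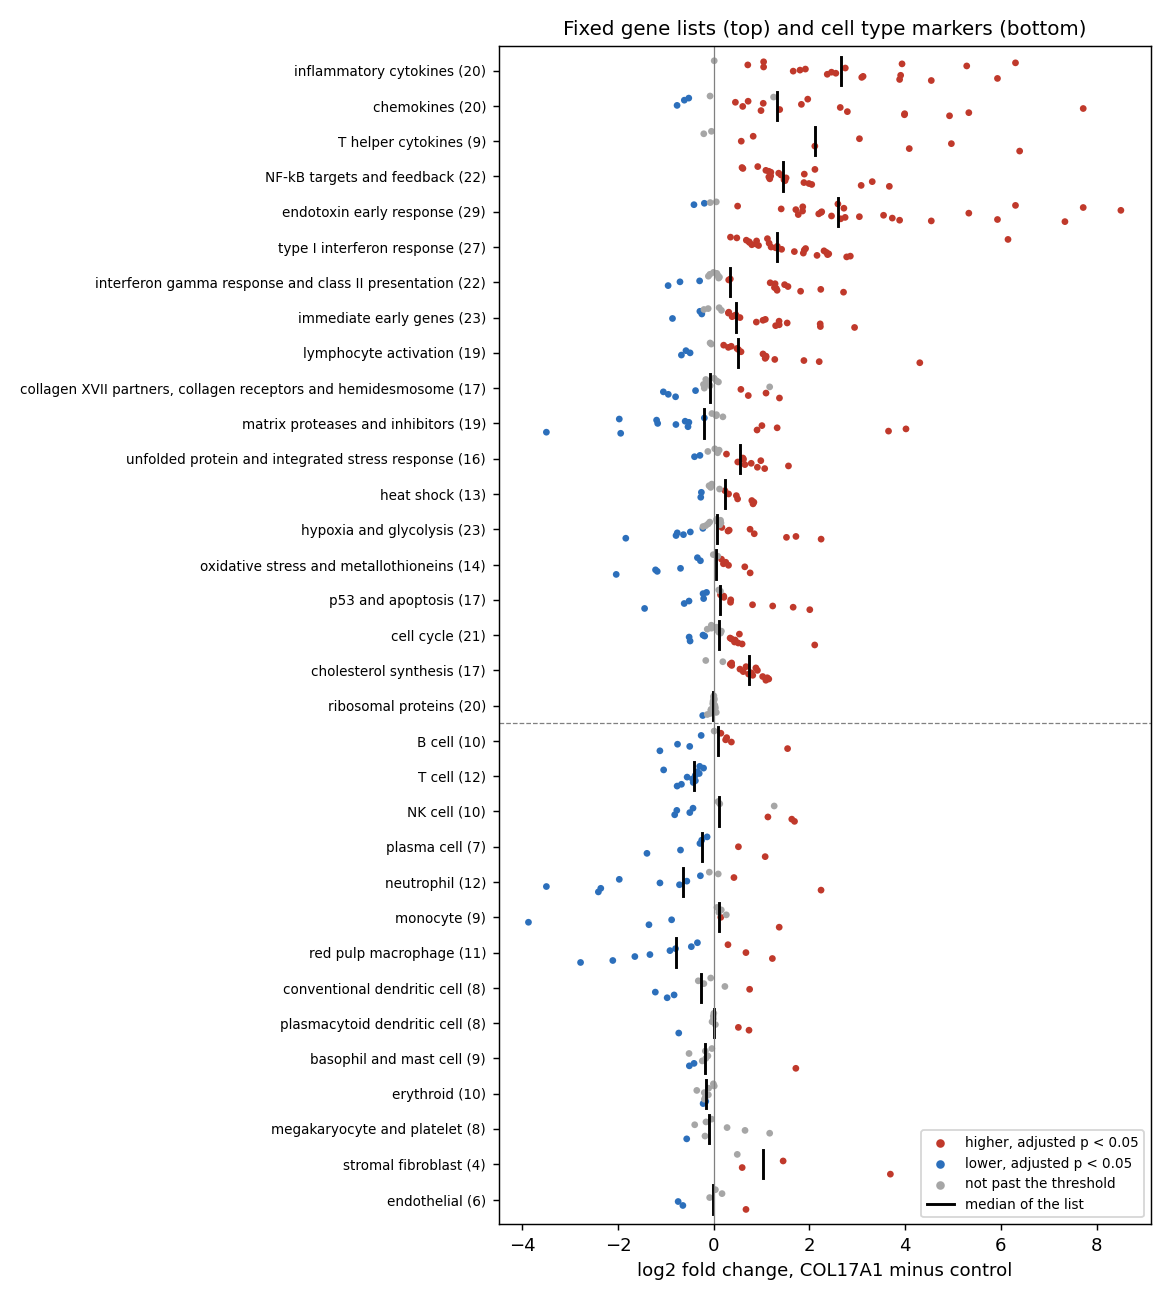
Log2 fold change (COL17A1 minus control) of each measured member of the 19 gene lists, above the dashed line, and of the 14 marker lists, below it, with the number of members in brackets. Points are genes, red if higher and blue if lower at adjusted p under 0.05 and grey otherwise, and the black bar is the list's median, such as 2.65 for inflammatory cytokines and -0.41 for T cell markers.

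All T cell markers measured were lower: 0 of 12 were higher, 12 lower and 0 not called, with 12 lower adjusted over the list alone. Cd5 fell by 0.76 ± 0.06, Cd2 fell by 0.67 ± 0.05, Lck fell by 0.43 ± 0.04 and Cd3e fell by 0.38 ± 0.04. The median was -0.41 at a limma camera adjusted p of 2.8e-04 (adjusted p = 0.227 with an estimated correlation). Neutrophil markers fell as a list, with 2 of 12 higher, 8 lower and 2 not called, the same adjusted over the list alone. Retnlg fell by 2.41 ± 0.06 and Cxcr2, a chemokine receptor, fell by 2.36 ± 0.09, while Lcn2, also in the endotoxin list, rose by 2.24 ± 0.06. Their median was -0.64 at a limma camera adjusted p of 0.0459 (adjusted p = 0.445 with an estimated correlation). The list no longer passed without control replicate 3 (limma adjusted p = 0.0532), COL17A1 replicate 3 (0.0504) or both (0.0546), with quantile normalisation (0.0559), probes above background on all 6 arrays (0.138), every probe on its own (0.0753) or the replicate block (0.0566). Over all alternatives by camera its adjusted p ranged from 0.00213 to 0.445. With normexp Cxcr2 stood at -1.54. Of 10 stromal fibroblast markers fixed, 6 were not tested because their probes failed the background filter, among them the collagen genes Col1a1 and Col3a1. The list rose with 3 of the 4 tested higher, 0 lower and 1 not called, 3 adjusted over the list alone, with a median of 1.02 at a limma camera adjusted p of 0.0459 (adjusted p = 0.230 with an estimated correlation). Of these, Pdgfrb was at least 3.34-fold higher, not well above background in the control (log2 change of 1.00 with normexp, under that bound), Pdpn rose by 1.45 ± 0.26 (0.57 with normexp) and Acta2 was called at 0.60 although its probes ranged from -0.13 to 0.60. That list also did not pass without COL17A1 replicate 1 (limma adjusted p = 0.0512) or COL17A1 replicate 3 (0.0504), with the mean of probes (0.0776), every probe on its own (0.0837) or a trended and robust variance (0.0516). Over all alternatives by camera its adjusted p ranged from 0.0103 to 0.230.

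Red pulp macrophage markers, of the cells that recycle iron from old red cells, were mostly lower, with 3 of 11 higher, 8 lower and 0 not called, the same adjusted over the list alone, but the list was not called (limma camera adjusted p = 0.0798). That depends on the processing, since the list was called lower with median scaling (limma adjusted p = 0.0368), cyclic loess (0.0495), normexp (0.0499), no filter on dim probes (0.00508), without COL17A1 replicate 2 (0.0474), without both arrays of number 2 (0.0461) and by fry (7.0e-05). Over all alternatives by camera its adjusted p ranged from 0.00508 to 0.391. The iron exporter gene Slc40a1 fell by 2.78 ± 0.06, Cd5l fell by 2.11 ± 0.08 and the complement gene C1qc fell by 1.65 ± 0.09, whereas Spic, the transcription factor of these cells, rose by 1.23 ± 0.06. Monocyte markers had 2 of 9 higher, 3 lower and 4 not called, the same adjusted over the list alone, with F13a1 lower at -1.35 ± 0.07 (-0.66 with normexp), and their median (0.11) and mean (-0.44) differ in sign (limma camera adjusted p = 0.810). Conventional dendritic cell markers had 1 of 8 higher, 3 lower and 4 not called, or 2 and 3 adjusted over the list alone (limma camera adjusted p = 0.335, and lower by fry at 5.9e-04). Sirpa fell by 0.97 ± 0.06 and Clec10a fell by 1.22 ± 0.10, while Zbtb46 rose by 0.75 ± 0.10. Plasmacytoid dendritic cell markers had 2 of 8 higher, 1 lower and 5 not called, the same adjusted over the list alone (limma camera adjusted p = 0.683, and higher by fry at 0.0306). Ccr9 fell by 0.73 ± 0.04, and Siglech stood at 0.04 from its brightest probe and -0.25 from the mean of its probes.

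B cell markers, the largest lymphocyte class of the spleen, had 5 of 10 higher, 4 lower and 1 not called, the same adjusted over the list alone (limma camera adjusted p = 0.810). Fcer2a, the low-affinity IgE receptor, rose by 1.54 ± 0.06, while Cd79b, a chain of the B cell receptor, fell by 1.12 ± 0.05 and Cd22 fell by 0.50 ± 0.06. The 2 probes of Fcer2a differed, at 1.54 and 0.17, and their mean gave 0.86. Natural killer cell markers had 3 of 10 higher, 4 lower and 3 not called, or 4 and 4 adjusted over the list alone, with the granzyme genes Gzmb up by 1.69 ± 0.07 and Gzma by 1.63 ± 0.08 and Klrd1 lower at -0.82 ± 0.04 (limma camera adjusted p = 0.749, and higher by fry at 0.00529). Plasma cell markers had 2 of 7 higher, 5 lower and 0 not called, the same adjusted over the list alone, where Sdc1 fell by 1.39 ± 0.07 and Irf4 rose by 1.08 ± 0.04 (limma camera adjusted p = 0.513, and lower without genes shared between lists at 0.0345). Basophil and mast cell markers had 1 of 9 higher, 2 lower and 6 not called, the same adjusted over the list alone, and the 1 higher was Hdc, the histamine-forming enzyme, at 1.72 ± 0.07 (limma camera adjusted p = 0.619). Erythroid markers had 0 of 10 higher, 2 lower and 8 not called, with 0 and 0 adjusted over the list alone (limma camera adjusted p = 0.248). Megakaryocyte and platelet markers had 0 of 8 higher, 1 lower (Vwf, -0.56 ± 0.08) and 7 not called, and 0 and 1 adjusted over the list alone, with a median of -0.10 and a mean of 0.09 (limma camera adjusted p = 0.879). Endothelial markers had 1 of 6 higher, 2 lower and 3 not called, the same adjusted over the list alone, with Egfl7 up by 0.67 ± 0.07 and Stab2 lower at -0.64 ± 0.10 (limma camera adjusted p = 0.858).

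In all, 12 of the 33 lists were higher and 2 lower by camera with its preset correlation. With an estimated correlation 3 lists remained called, the inflammatory cytokines and the NF-kB list at a limma adjusted p of 0.0226 each and the type I interferon list at 0.0194, and 0 lists lower. With fry 18 lists were higher and 5 lower. The control arrays lay in 1 column of the slide and the COL17A1 arrays in the other, so slide column and group coincide; the spike-in RNAs detected on all arrays differed between them by a median absolute log2 difference of 0.0548. Among called genes with several probes, all probes moved the same way in 3778 of 4486.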

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

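The fit without the 2 arrays marked for evaluation was chosen after the result was seen. Over the alternatives the log2 changes of named genes stayed on their side of the threshold, called genes in their direction, in 3081 of their values, lost the call in 43, gained it in 13 and reversed in 3. The reversed values came with the mean of probes: Itga6 -0.89, Rps20 0.18 and Siglech -0.25, where probes of 1 gene differ in sign. A 2-fold minimum left 923 genes higher and 920 lower, and every probe on its own gave 7353 higher, since it counts more features. Lists numbered 3 higher and 0 lower with an estimated correlation and 18 higher and 5 lower with fry, which tests a list against no change. There was 1 list lower with quantile normalisation, with probes above background on all 6 arrays, with every probe on its own and with the replicate block, the neutrophil list having lost its call. There were 3 lower with median scaling, cyclic loess, normexp and no filter on dim probes, where the red pulp macrophage list gained a call, and without genes shared between lists, where the plasma cell list did. Lists higher numbered 14 with every probe on its own, and 11 with probes above background on all 6 arrays, the mean of probes or a trended and robust variance. Leaving out arrays gave 3666 to 4545 genes higher, 4116 to 5593 lower, 11 to 12 lists higher and 1 to 3 lists lower. The single list lower came without control replicate 3, without COL17A1 replicate 3 and without both arrays of number 3, and the 3 lists without COL17A1 replicate 2 and without both arrays of number 2. The replicate block gave 4431 genes higher and 5308 lower. Deviations of same-numbered arrays correlated at r = 0.07, -0.11 and -0.07 over genes, and those of different numbers at -0.10 to 0.17. With 3 arrays per group this cannot tell whether equal numbers share a mouse. Without the 2 arrays marked for evaluation 3733 genes were higher and 4514 lower, 7893 of the calls kept their direction, and lists were 12 higher and 2 lower. Higher genes made up 41.8% to 50.2% of calls over the scalings, 45.6% as reported. Signal over background limits the dim genes, and the array number limits the rest.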

Other observations

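The gene groups of the first paragraphs, and the tests on endotoxin, on the spread of marker falls, on rising macrophage markers, on dilution by induced transcripts and on the metallothionein probes, were chosen after the result was seen. Ribosome biogenesis genes, which build ribosomes in the nucleolus, rose with COL17A1: 29 of 29 measured members were higher and 0 lower, with a median log2 change of 1.37. Polr1b, a subunit of RNA polymerase I, rose by 1.77 ± 0.07, Wdr43 by 1.72 ± 0.05 and Nop58 by 1.58 ± 0.04, while ribosomal protein genes had a median of -0.01. Genes of macrophage lipid handling and lysosomes fell in 16 of 16 measured members, with a median of -1.33. Csf1r, the receptor of the macrophage growth factor, fell by 1.64 ± 0.10, Apoe fell by 1.28 ± 0.05, Lyz2, a lysozyme gene, fell by 1.37 ± 0.07 and the lysosomal protease gene Ctsk fell by 2.16 ± 0.06.

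Among sphingosine phosphate receptors and other genes of lymphocyte traffic, 8 of 12 were lower, 2 higher and 2 not called, with a median of -1.55. S1pr1, the receptor that lets lymphocytes leave lymphoid organs, fell by 2.14 ± 0.06, S1pr4 fell by 2.14 ± 0.07 and Klf2, the transcription factor that maintains S1pr1, fell by 1.94 ± 0.05, whereas Cxcr5 rose by 1.14 ± 0.06. Members of these lists were picked in part because their values had been seen, so limma's camera is no independent evidence for them. With an estimated correlation the limma adjusted p was 0.0715 for each of the 3 lists.

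Between COL17A1 and control 10551 genes changed. Of the 10 ways to split the 6 arrays into 3 and 3, only 1, the real one, gave as many, and the highest of the others gave 1 gene. With 10 splits the share cannot fall under 0.05. In the other splits a large difference between the groups adds to the spread within each side. Their low counts thus follow from that difference whatever its cause, and the gap in counts decides nothing further.

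The cytokine, NF-kB, endotoxin and interferon lists rose together, with 88 of their 93 genes higher, 2 lower and a median log2 change of 1.87. Spike-in RNAs, added to each sample alike, differed between the groups, and so between the slide columns, by a median absolute log2 difference of 0.0548. They were scaled to each array's percentile like the genes, which removes an even difference in position or labelling. The value therefore speaks only against a shift of the spike-ins relative to the other probes. Slide column and group coincide, so effects of position on single genes cannot be told apart from COL17A1. Without the 2 arrays marked for evaluation the median was 1.89, which argues against their noise. Endotoxin in the protein cannot be told apart from COL17A1 itself: 52 of the 56 measured genes of the endotoxin and type I interferon lists were higher, but these lists make up the pattern, so the count does not speak for endotoxin over another stimulus. A response to COL17A1 is the explanation the design names, and no sample given endotoxin alone was analysed here.

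T cell markers and most red pulp macrophage markers were lower. Each array was scaled to its own percentile, so the ribosomal protein median of -0.0073 alone cannot show whether induced transcripts diluted the rest. An even dilution would shift ribosomal protein genes and these markers alike. The medians were -0.41 for T cell and -0.80 for red pulp macrophage markers, which argues against even dilution as the cause of the falls. Among the 8 falling macrophage markers the largest and smallest fall differed by 2.44, with a standard error of 0.112, and among the 12 T cell markers by 0.834, with a standard error of 0.214, which is 3.91 standard errors and short of the 4 asked for. The ratio of the SD of the falls to their standard error, tried only after the T cell gap had fallen short, was 2.86 for T cells and 10.3 for the macrophage markers. Only falling markers entered, and other cells express some of them, such as Hmox1, so unequal falls exclude nothing. Of the 11 macrophage markers measured, 3 rose, Spic by 1.23 ± 0.06, Axl by 0.67 ± 0.05 and Vcam1 by 0.30 ± 0.06, named after their values were seen. Fewer of these cells raise none of their markers, which argues against a lower share as the whole cause of the list's changes. Since other cells may have raised these 3, a lower share as the cause of the 8 falls stays open. For T cells, with 0 of 12 markers higher, a lower share cannot be told apart from lower transcript levels within the cells.

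Mt1, Mt2 and Slc30a1, which zinc induces through a shared transcription factor, had log2 changes of -1.22, -1.18 and -2.04. By the mean of its 2 probes Mt1 stood at -0.87. Whether the near-identical metallothionein probes cross-hybridise stays open, since the Slc30a1 value is itself part of the pattern. Less available zinc may be an explanation: Slc39a10, a zinc importer gene that low zinc raises, was 0.97 ± 0.11 higher, in a test fixed before its value was seen. Of 12 zinc importer genes, listed afterwards, 5 were higher, 2 lower and 5 not called. Among all genes tested 4813 of 21288 were higher, so the rise of 1 gene is weak evidence. Zinc itself was not measured, and other regulation of Slc39a10 by the stimulus stays untested.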
